A study of Caenorhabditis elegans with 8 samples.

How the data were processed

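RNA sequencing of whole-body total RNA from C. elegans of strain DCL569 was analysed in 8 libraries, 2 in each of 4 groups, from the deposited table of gene values. Per the labels, RNAi against inx-14 or the vector L4440 was given by feeding, followed by OP50 or PA14. Groups were taken from the titles (CT_OP, KD_OP, CT_PA, KD_PA), because the genotype label gives L4440 for all OP50 and inx-14 RNAi for all PA14 libraries and so cannot be joined with a design of 4 groups; the numbers 1 and 2 are the replicate numbers of the titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

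Per the submitters' processing notes, base calls were made with CASAVA, reads were aligned with HISAT2 and genes were counted with featureCounts. Versions, genome build and normalization tool are not given in the sources used here. The unit of the deposited values is a signal: although the file is named for FPKM, the values are gene counts that the authors divided by one size factor per library, without division by gene length. This was tested on the values, which in each library were whole multiples of the value of 1 read within 0.01 read in 100% of genes. In KD_PA 2 the value of 1 read, 1.0035, lies near 1, though the largest deviation from whole multiples was only 4.6e-05 read there. As a precaution, count-based alternatives were run with all 8 and with 7 libraries.

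Depth was 21647901 and 18828975 recovered reads in CT_OP, 19724014 and 19351888 in KD_OP, 19464095 and 19775009 in CT_PA, and 20785080 and 18572699 in KD_PA. The gene with most reads took from 2.42% (vit-6, CT_OP 1) to 6.18% (vit-5, KD_OP 1) of a library, and the top 10 genes from 10.0% to 22.0%. The table held 15488 genes, of which 15434 carried WormBase identifiers and 54 were unannotated, the latter with 0.016% of reads, and no gene had fewer than 20 reads in total. The position of inx-14 was taken from WBcel235 (Ensembl release 115), which holds 15412 of the identifiers and may differ from the annotation the authors used.

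Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, with one mean per group over all 8 libraries, empirical Bayes moderation with an intensity trend (4 residual and 4.54 prior degrees of freedom), and Benjamini-Hochberg adjustment. Genes with a value of at least 1 in at least 2 libraries were tested, which kept all 15488. A gene passed, was called, or rose or fell, at an adjusted p under 0.05. The comparisons were KD_OP against CT_OP, KD_PA against CT_PA, CT_PA against CT_OP, KD_PA against KD_OP, and the interaction. The groups, comparisons, tests, named-genes rule and main alternatives were fixed before the data were examined. That plan assumed FPKM, and the same limma test was kept for the values found.

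Tests of 35 gene lists written from general knowledge of C. elegans genes used camera in limma with a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists of a comparison. Counts of called members were also made with p adjusted over the list alone. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) was used to read the table and draw figures.

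Named genes were chosen by a rule: inx-14; per comparison the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap between the groups and whose higher group mean was at least 5 (for the interaction 5 each way); and per list up to 4 called members of lowest adjusted p, or 2 of lowest p where none was called. In the description of single libraries, acdh-1 and irg-3 were picked after their values were seen. For a gene without reads in a group, the ratio is given as at least the fold over a floor of 3 reads per library. With 1 to 3 reads in a group, it is the ratio of reads with an exact (Clopper-Pearson) 95% counting interval.

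The alternatives listed in advance were a pseudocount of 0.1, no filter, a filter at a mean of 5, median-ratio scaling, quantile normalization, the replicate number as a block, no variance trend, only the groups compared, a log2 fold change of at least 1 in addition to the threshold, and leaving out each library. Alternatives chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, scaling of each library to the median ratio of 62 muscle and neuron genes with a mean of at least 20, and leaving out KD_OP 2 and KD_PA 1 together. DESeq2 had been listed in advance only for a table of raw counts. The closing section gives their effect. The rule that judged the place of KD_OP 2 and KD_PA 1 was revised 2 times after its values were seen. With the standard error over genes as spread, it had favoured an exchange of the 2 names and excluded weak exposure and a response of immune genes alone. With the larger difference between CT replicates it first still favoured the exchange, by a form that more spread made easier to pass, and in the symmetric form used here all 3 stayed open.

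On simulated data limma recovered 11.8%, 69.7% and 93.9% of genes changed by 1, 2 and 3 on the log2 scale in KD_OP. Of the genes then called 7.9% were false, and 10.8% with the changes placed in CT_PA. Both runs used the same means and dispersions, taken over all 8 libraries, so neither carries the spread of its own comparison. The set test was simulated for CT_PA against CT_OP only, with lists of 30 genes, and called 20 of 20 lists changed by 0.7 on the log2 scale and 0 of 200 unchanged lists. Simulated genes varied independently, whereas the estimated correlation was 0.447 in the p38-linked and 0.742 in the germline list. The simulation therefore does not test the preset correlation in such lists. Survival, bacterial counts and alternative splicing were not analysed here.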

Results

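The transcriptome of whole Caenorhabditis elegans was measured by RNA sequencing in 8 libraries. The worms were of the strain DCL569, in which RNA interference by feeding acts in the germline, and received either the empty vector L4440 or an RNAi clone against inx-14. They were then kept on Escherichia coli OP50, the usual laboratory food, or infected with Pseudomonas aeruginosa PA14, a bacterium that kills the worm through the intestine. The titles give 4 groups of 2 libraries, named here as in the titles: CT_OP and CT_PA (vector) and KD_OP and KD_PA (inx-14 RNAi). The series title frames the question as whether gonadal gap junctions act through Notch signalling on intestinal immunity, by way of the p38 kinase PMK-1 and the lysosome. Reads recovered per library ranged from 18572699 to 21647901. The values below are normalised read counts as deposited, and every group value rests on n = 2 libraries.

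The level of inx-14 separated the KD from the CT titles in every library. inx-14 (WBGene00002136) encodes an innexin, a gap junction subunit of germ cells, and lies on the minus strand of chromosome I from 7350309 to 7352235 in WBcel235. Its normalised read count was 3516 and 3326 in CT_OP, 103 and 75.8 in KD_OP, 3957 and 3704 in CT_PA, and 645 and 817 in KD_PA. The log2 fold change was -5.26 ± 0.19 (SE) in KD_OP against CT_OP (limma, adjusted p = 3.32e-07) and -2.40 ± 0.19 in KD_PA against CT_PA (adjusted p = 0.000188). One genotype label contradicted these titles, since it gives L4440 for all OP50 libraries and inx-14 RNAi for all PA14 libraries. The inx-14 levels followed the titles, and the groups are those of the titles throughout.

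**Figure D1:**
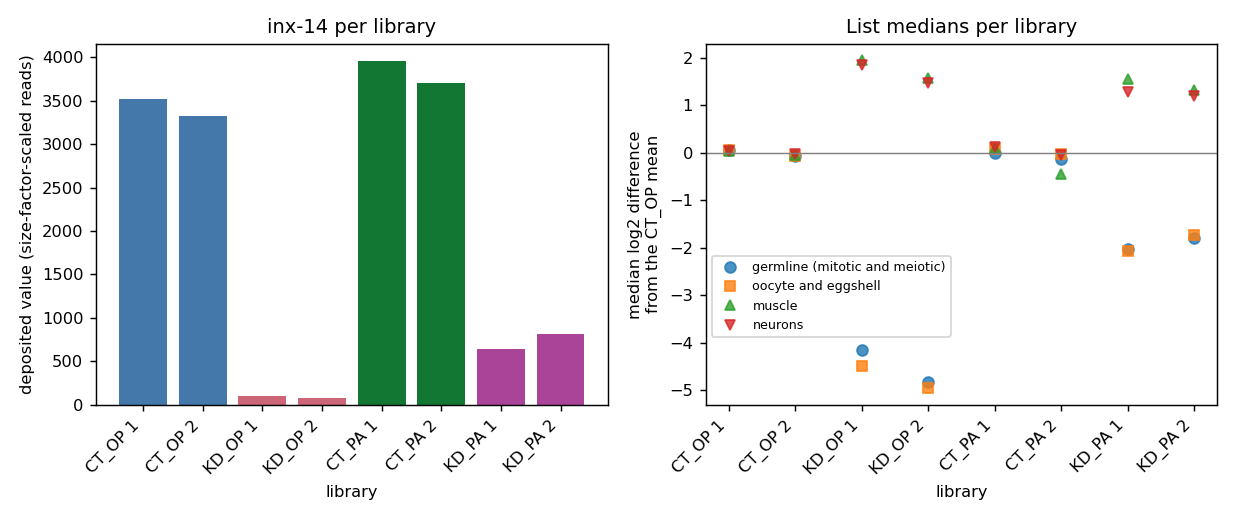
Left, normalised read count of inx-14 in each of the 8 libraries (bars, linear axis from 0). Right, median log2 difference of each library from the CT_OP mean over the genes of the germline, oocyte, muscle and neuron lists, where the germline list lies at -4.15 and -4.82 in KD_OP and at -2.03 and -1.80 in KD_PA.

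A pair of libraries stood apart from their groups. The first principal component held 76.9% of the variance and parted KD from CT libraries. The second held 8.3%, on which CT_OP lay at 40.6 and 46.5 and CT_PA at -37.4 and -50.6. On that component KD_OP 1 lay at 34.4 and KD_PA 2 at -40.8, while the library labelled KD_OP 2 lay at -19.4 and the library labelled KD_PA 1 at 26.6. On the first component both lay with their titles, KD_OP at 153.9 and 170.3 and KD_PA at 61.3 and 55.3. Over all genes the log2 values correlated with Pearson r = 0.965 between the KD_OP libraries and 0.971 between the KD_PA libraries, against 0.928 to 0.944 between KD_OP and KD_PA libraries. acdh-1, an acyl-CoA dehydrogenase of propionate breakdown, shows the same arrangement. Its normalised read count was 17800 and 16880 in CT_OP and 36 and 4.9 in CT_PA, but 18320 in KD_OP 1, 2857 in KD_OP 2, 30460 in KD_PA 1 and 450 in KD_PA 2. irg-3, an infection response gene, read 161.2 and 118.6 in CT_OP and 1630 and 1479 in CT_PA, against 765 and 4323 in KD_OP and 863 and 3303 in KD_PA. Counts of called genes and the medians of several lists are therefore also given without KD_OP 2 and KD_PA 1, a choice made after seeing the data.

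**Figure D2:**
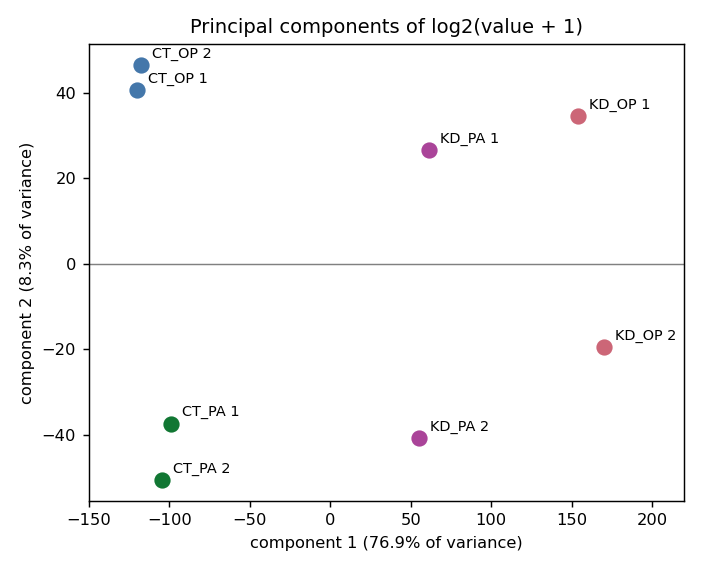
Positions of the 8 libraries on the first and second principal components of log2(value + 1), with the share of variance on each axis. KD_OP 2 (-19.4) lies on the side of the CT_PA libraries on the second component and KD_PA 1 (26.6) on the side of the CT_OP libraries.

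**Figure D3:**
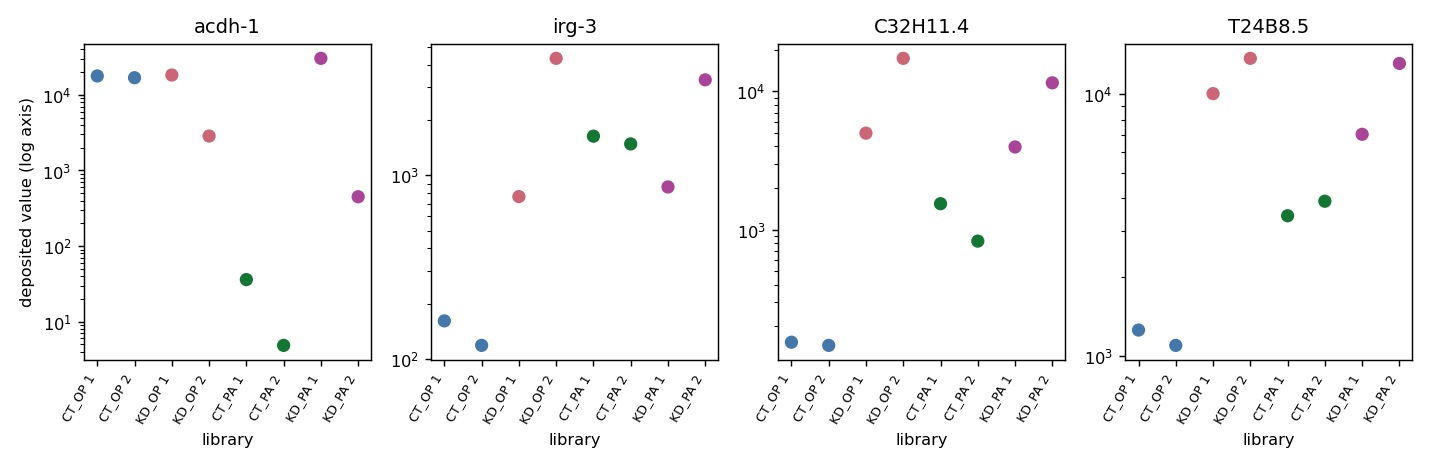
Normalised read count of 4 genes in each library, on log axes. acdh-1 was at 36 and 4.9 in CT_PA but at 30460 in KD_PA 1, and C32H11.4 was at 17350 in KD_OP 2 against 4992 in KD_OP 1.

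The effect of inx-14 RNAi in worms on OP50 was read from KD_OP against CT_OP. Transcripts of the germline fell together. Of 48 measured genes of mitotic and meiotic germ cells 47 fell, with a median log2 fold change of -4.46, among them daz-1 at -4.71 ± 0.17 (SE) and cpb-3 at -4.72 ± 0.16. Of 29 oocyte and eggshell genes 27 fell and 1 rose, with a median of -4.74, including the maternal RNA-binding proteins pos-1 (-4.97 ± 0.17) and puf-5 (-4.88 ± 0.18) and the eggshell proteoglycan cpg-3 (-5.01 ± 0.18). All 31 cell cycle and DNA replication genes fell, with a median of -4.68, including the helicase subunit mcm-5 (-4.94 ± 0.17) and the kinase cdk-1 (-4.89 ± 0.17). Genes of muscle and neurons rose, 28 of 30 muscle genes with a median of 1.80 and 32 of 36 neuronal genes with a median of 1.64. The set test camera gave adjusted p = 1.63e-14, 2.4e-09, 2.51e-12, 5.07e-07 and 8.1e-07 for these 5 lists, and adjusted p = 0.383, 0.383, 0.358, 0.45 and 0.293 with an estimated correlation.

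Most genes of the Notch list fell in KD_OP. Of 30 Notch pathway genes and targets 23 fell and 3 rose, with a median of -2.54 (-2.49 with its 2 near-zero genes at the floor of 3 reads). The members that fell included lst-1 (-3.90 ± 0.16) and sygl-1 (-4.55 ± 0.18), targets of the Notch receptor GLP-1 in germline stem cells, and the ligand gene apx-1 (-3.63 ± 0.16). By camera the list had adjusted p = 0.000696 and adjusted p = 0.252 with an estimated correlation. It shares glp-1 and fbf-2 with the germline list, whose median was -4.46. Whether Notch genes fell beyond that loss of germline transcripts was not tested. Of 25 innexins 12 rose and 6 fell; those that fell included inx-22 (-4.97 ± 0.16), inx-21 (-4.75 ± 0.20) and inx-3 (-4.66 ± 0.32). The innexin list as a whole was not called (median 0.74, mean -0.38, -0.83 when scaled to muscle and neuron genes, camera direction up, adjusted p = 0.231). Of 77 ribosomal protein genes 75 fell, with a median of -1.33 and a larger fall of rpl-11.1 (-4.71 ± 0.30; list adjusted p = 5.07e-07, and adjusted p = 0.602 with an estimated correlation). Within otherwise rising lists, tdc-1, the tyrosine decarboxylase of octopamine synthesis, fell by 4.09 ± 0.16 while tbh-1, the next enzyme of that pathway, rose by 2.62 ± 0.19. sepa-1, a receptor for the autophagy of P granule proteins, had a log2 fold change of -5.48 ± 0.52, in an autophagy list of 31 genes of which 17 fell and 7 rose (median -0.89, adjusted p = 0.282). That median depended on scaling, at -0.05 under quantile normalization and at -2.55 with 28 falls when scaled to muscle and neuron genes (adjusted p = 0.00811). The medians without KD_OP 2 and KD_PA 1 were -4.15 for germline, -4.49 for oocyte, -4.37 for cell cycle, 1.95 for muscle, 1.85 for neuron, -2.53 for Notch, 0.82 for innexin and -1.5 for ribosomal genes.

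Immune effectors linked to PMK-1 rose in KD_OP. Of 15 such genes 14 rose and 0 fell, over all genes tested and when adjusted over the list alone, with a median log2 fold change of 3.25. T24B8.5, a much used PMK-1 reporter gene, rose by 3.32 ± 0.29 (SE), C17H12.8 by 3.57 ± 0.37, catp-3 by 3.19 ± 0.46 and C32H11.4 by 5.95 ± 0.63. The camera test gave adjusted p = 0.000206, and adjusted p = 0.398 with an estimated correlation. C32H11.4 read 4992 in KD_OP 1 and 17350 in KD_OP 2 against 154 and 146 in CT_OP, and the list median was 3.1 without KD_OP 2 and KD_PA 1. The 11 kinases and regulators of the PMK-1 pathway itself showed 4 rises and 1 fall (median 0.34, adjusted p = 0.257). Their median was 0.79 without KD_OP 2 and KD_PA 1, but -1.31 when scaled to muscle and neuron genes. In the ZIP-2-linked infection response 6 of 11 genes rose and 1 fell, with zip-2 at 1.74 ± 0.26 and irg-3 at 3.71 ± 0.78, but the list was not called (median 2.27, adjusted p = 0.0733, and adjusted p = 0.602 with an estimated correlation). Without KD_OP 2 and KD_PA 1 its median was 1.77, with 4 rises and 1 fall (adjusted p = 0.0411), and it was also called without KD_PA 1 (adjusted p = 0.0391) or KD_PA 2 (adjusted p = 0.0392), with the replicate block (adjusted p = 0.0382), with only the 2 groups (adjusted p = 0.0135) and with muscle and neuron scaling (adjusted p = 0.00311).

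Lysosomal genes were higher in KD_OP as well. Of 63 lysosomal hydrolases and membrane proteins 45 rose and 3 fell, the same counts as when adjusted over the list alone, with a median of 1.82; scaled to muscle and neuron genes, 10 rose and 17 fell. The hexosaminidase hex-1 rose by 2.43 ± 0.17 and the cathepsin gene cpz-2 by 2.51 ± 0.19, while cup-5, which encodes the lysosomal channel mucolipin, had a log2 fold change of -2.12 ± 0.17. The camera test gave adjusted p = 8.89e-07, and adjusted p = 0.197 with an estimated correlation. Of 21 vacuolar ATPase subunits 9 rose and 3 fell, with vha-6 at 1.68 ± 0.19 and vha-18 at -4.62 ± 0.27 (median 0.54, adjusted p = 0.0403, and adjusted p = 0.702 with an estimated correlation). The call of the vacuolar ATPase list was lost without CT_OP 1 (adjusted p = 0.051), CT_OP 2 (0.0866) or KD_OP 1 (0.0795, median 0.37) and with no variance trend (0.0637). Of 13 lysozymes 7 rose, including lys-8 at 2.73 ± 0.31 (median 1.93, 1.38 with 1 near-zero gene at the floor, adjusted p = 0.0226, and adjusted p = 0.252 with an estimated correlation). Scaled to muscle and neuron genes, the lysozyme median was 0.3, with 3 rises and 1 fall. Intestinal genes rose in 18 of 25 cases and fell in 1, with the desaturase fat-6 at 2.34 ± 0.19 (median 1.53, adjusted p = 0.000206, and adjusted p = 0.197 with an estimated correlation). The yolk protein gene vit-5 rose by 1.59 ± 0.51, a call lost without CT_OP 1, CT_OP 2 or KD_OP 1 (1.6, 1.57 and 1.41). With KD_OP 2 and KD_PA 1 left out, medians were 1.71 for lysosomal, 0.68 for vacuolar ATPase, 1.54 for lysozyme and 1.68 for intestinal genes.

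The largest rises in KD_OP were of genes nearly silent in CT_OP. H39E23.3 had no reads in CT_OP and 8368 and 12690 normalised reads in KD_OP, at least 3500-fold higher, against a floor of 3 reads per library. scl-20 was at least 172-fold higher, the collagen gene col-36 at least 131-fold and F17B5.1 at least 68.6-fold. D1086.9 was higher by a ratio of reads of 531 (exact 95% counting interval 147 to 4390) and F23F1.2 by 590 (105 to 23300). The dehydrogenase gene dhs-26 rose by 9.98 ± 0.40, the ferritin gene ftn-1 by 7.70 ± 0.41, C30G12.2 by 7.20 ± 0.22 and F56D6.9 by 7.0 ± 1.13. The glucuronosyltransferase ugt-41 rose by 4.64 ± 0.16 and the superoxide dismutase sod-3 by 4.01 ± 0.32. Intervals and floors here cover counting error only.

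The largest falls in KD_OP included dsl-2, a gene of the family of Notch ligands, at -7.0 ± 1.00, Y106G6D.2 at -6.67 ± 0.77 and T25E12.6 at -6.36 ± 0.55. The Skp1-related genes skr-10 (-6.43 ± 0.87) and skr-9 (-6.28 ± 0.81), the transcription factor gene zip-8 (-6.29 ± 1.1) and clec-266 (-6.28 ± 1.13) were among them. R11.4 was at least 44.8-fold lower, F48E3.6 was lower by a ratio of reads of 304 (54.2 to 12100) and btb-11 by 145 (39.6 to 1200).

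In all, 11679 of 15488 genes passed the limma test, 5464 higher and 6215 lower in KD_OP, and 10457 (4506 higher, 5951 lower) without KD_OP 2 and KD_PA 1. The split depended on the scaling between libraries, which stays open when most genes change. When libraries were scaled to muscle and neuron genes, 605 genes were higher and 8406 lower, and the median of all genes moved from 0.14 to -1.43 (0.41 under quantile normalization and 0.64 in edgeR). Under that scaling the p38-linked median was 1.6 with 6 rises, the ZIP-2-linked 0.62 and the lysosomal 0.17. Those of intestine (-0.11) and vacuolar ATPase (-1.12) changed sign, as did vit-5 (-0.07). The germline (-6.10), oocyte (-6.39), ribosomal (-2.99) and Notch (-4.15) medians stayed negative. The neuron median (-0.01) was near 0 by the construction of that scaling.

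**Figure D4:**
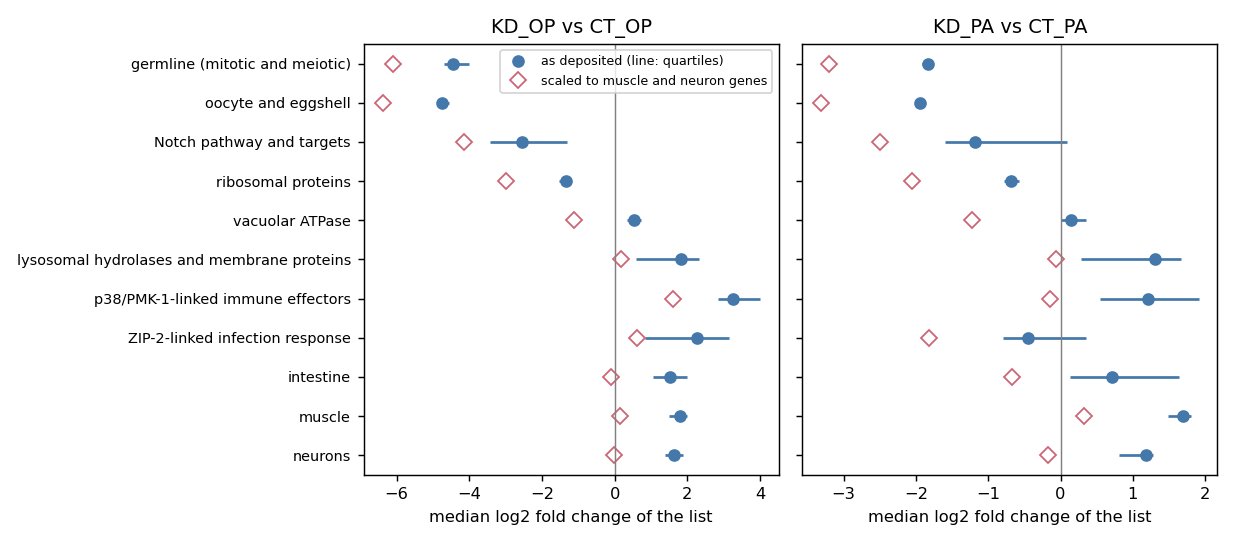
Median log2 fold change of 11 gene lists in KD_OP against CT_OP (left) and KD_PA against CT_PA (right), from the deposited values (filled circles, lines spanning the quartiles of the list) and after scaling the libraries to muscle and neuron genes (open diamonds). The lysosomal median moved from 1.82 to 0.17 on OP50 and from 1.31 to -0.06 on PA14, and the p38-linked median from 3.25 to 1.6 and from 1.21 to -0.14.

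The same RNAi comparison in infected worms was KD_PA against CT_PA. Germline transcripts fell here too, by smaller amounts. Of the 48 germline genes 47 fell, with a median log2 fold change of -1.83, including daz-1 (-1.99 ± 0.17, SE) and cpb-3 (-1.85 ± 0.16). Of 29 oocyte genes 26 fell, with a median of -1.94, including pos-1 (-1.93 ± 0.17) and lin-41 (-2.0 ± 0.18), a regulator of oocyte growth. All 31 cell cycle genes fell (median -1.88), 29 of 30 muscle genes and 29 of 36 neuronal genes rose (medians 1.70 and 1.18), with tni-3, a troponin gene, at 1.91 ± 0.22 and tbh-1 at 2.19 ± 0.19. The camera test gave adjusted p = 6.98e-14, 5.11e-09, 4.21e-12, 5.84e-09 and 4.01e-06 for the germline, oocyte, cell cycle, muscle and neuron lists, and adjusted p = 0.397, 0.397, 0.365, 0.397 and 0.336 with an estimated correlation.

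Of the 30 Notch genes 16 fell and 3 rose in KD_PA, with a median of -1.18. lst-1 was at -1.80 ± 0.16, sygl-1 at -1.95 ± 0.18 and lag-1, the transcription factor of the pathway, at -1.61 ± 0.15 (list adjusted p = 0.00635, and adjusted p = 0.336 with an estimated correlation). The germline median was -1.83, and a Notch fall beyond it was not tested for. The germline innexins inx-22 (-1.99 ± 0.16) and inx-21 (-1.58 ± 0.20) fell, in a list with 11 rises and 6 falls among 25 genes (median 0.65, but -0.73 when scaled to muscle and neuron genes; adjusted p = 0.213). Of the 77 ribosomal protein genes 51 fell and 2 rose (median -0.68, adjusted p = 1.88e-05, and adjusted p = 0.644 with an estimated correlation). With KD_OP 2 and KD_PA 1 left out, medians were -1.72 for germline, -1.8 for oocyte, -1.79 for cell cycle, 1.54 for muscle, 1.14 for neuron, -1.16 for Notch, 0.54 for innexin and -0.53 for ribosomal genes, of which 15 then fell.

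Of the 15 p38-linked effectors 8 rose and 0 fell in KD_PA, also when adjusted over the list alone, with a median of 1.21. catp-3 rose by 3.66 ± 0.46, C17H12.8 by 1.81 ± 0.37, T24B8.5 by 1.39 ± 0.29 and K08D8.5 by 2.01 ± 0.47. By camera the list had adjusted p = 0.0175, and adjusted p = 0.584 with an estimated correlation. T24B8.5 read 7029 in KD_PA 1 and 13110 in KD_PA 2 against 3433 and 3902 in CT_PA, and without KD_PA 2 the list was not called (adjusted p = 0.141, median 0.81). Without KD_OP 2 and KD_PA 1 the median was 1.84, with 9 rises. Of the 63 lysosomal genes 40 rose and 3 fell, over all genes and when adjusted over the list alone, with a median of 1.31 (adjusted p = 3.99e-06, and adjusted p = 0.24 with an estimated correlation); scaled to muscle and neuron genes, 7 rose and 19 fell. The aspartyl protease gene asp-13 rose by 3.66 ± 0.38, the sphingomyelinase gene asm-3 by 4.80 ± 0.52, cpz-2 by 1.81 ± 0.19 and hex-1 by 1.59 ± 0.17. The lysozyme genes lys-7 and lys-8 rose by 3.73 ± 0.63 and 1.83 ± 0.31. In the ZIP-2-linked list 1 gene rose and 1 fell, and the list was not called (median -0.45, mean -0.10, camera direction up, adjusted p = 0.936; median 1.01 without KD_OP 2 and KD_PA 1, -1.26 without KD_PA 2 and -0.78 without CT_PA 1, also not called). Among 21 vacuolar ATPase genes 3 rose and 2 fell, with vha-6 at 0.71 ± 0.19 (0.47 and not called without CT_PA 2; list median 0.15, adjusted p = 0.399, and median -0.02 without CT_PA 2). Under quantile normalization the vacuolar ATPase list was called, with a median of 0.50 (adjusted p = 0.000778), and with muscle and neuron scaling it was called with a median of -1.23 (adjusted p = 0.00817). Medians without KD_OP 2 and KD_PA 1 were 1.25 for lysosomal, 1.69 for lysozyme and 0.07 for vacuolar ATPase genes.

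The largest rises in KD_PA included the metallothionein genes. The metallothionein gene mtl-1 rose by 10.31 ± 1.15, and mtl-2 was higher by a ratio of reads of 678 (exact 95% counting interval 121 to 26800). H39E23.3 and scl-20 had no reads in CT_PA and were at least 3570-fold and 179-fold higher. D1086.9 was higher by a ratio of 1920 (344 to 75800), dhs-26 rose by 10.38 ± 0.40, ftn-1 by 8.02 ± 0.41, F56D6.9 by 7.89 ± 1.13 and comt-4 by 7.82 ± 0.76. Among smaller rises, the cytochrome P450 genes cyp-35A3 and cyp-35C1 rose by 5.50 ± 0.45 and 4.02 ± 0.31, ugt-41 by 4.57 ± 0.16 and sod-3 by 3.81 ± 0.32. acdh-1 rose by 7.97 ± 1.74, with the uneven library values given above. Among the largest falls, which were smaller than the largest rises, the desaturase gene fat-7 was at -3.39 ± 0.93, erp-44.3 at -3.37 ± 0.83 and M162.12 at -3.21 ± 0.65, and B0250.11, nstp-3 and Y60A9.2 were at least 4.26-fold, 3.11-fold and 2.76-fold lower. phat-5, T10C6.9, wrt-2 and R09A8.9 were lower by ratios of reads of 19.8 (5.09 to 170), 29.4 (4.83 to 1210), 16.6 (5.32 to 83.6) and 13.2 (4.16 to 67.1). The calls of fat-7 (-3.15 without CT_PA 1, -2.19 without KD_PA 1), erp-44.3 (-2.39 without KD_PA 2), wrt-2 (-2.48 without CT_PA 2, -2.3 without KD_PA 1), R09A8.9 (-2.26 without KD_PA 1) and phat-5 (without CT_PA 1, CT_PA 2 or KD_PA 1; range -4.27 to -2.68) were lost with single libraries left out.

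In this comparison 9450 genes passed the limma test, 4417 higher and 5033 lower in KD_PA, and 7795 (3083 higher, 4712 lower) without KD_OP 2 and KD_PA 1. Scaled to muscle and neuron genes, 557 genes were higher and 7865 lower, and the median of all genes moved from 0.14 to -1.17 (-0.05 under quantile normalization, 0.31 in edgeR). The p38-linked (-0.14), lysosomal (-0.06) and vacuolar ATPase (-1.23) medians and vha-6 (-0.67) changed sign. The germline (-3.2), oocyte (-3.31) and Notch (-2.50) medians stayed negative. The neuron median (-0.17) was near 0 by the construction of that scaling.

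The RNAi differences on both bacteria overlapped. Between the lists of called genes, 3877 rose in both comparisons against 1558 by independent overlap, 4968 fell in both against 2020, and 8 went opposite ways. inx-14, dhs-26, ftn-1 and H39E23.3 were among the shared genes. Scaled to muscle and neuron genes, 285 rose and 7435 fell in both, and without KD_OP 2 and KD_PA 1 these counts were 2698 and 4604. Across the 15488 genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.851 and Spearman rho = 0.872, and the slope of the PA14 on the OP50 differences through 0 was 0.514. These comparisons share no libraries.

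**Figure D5:**
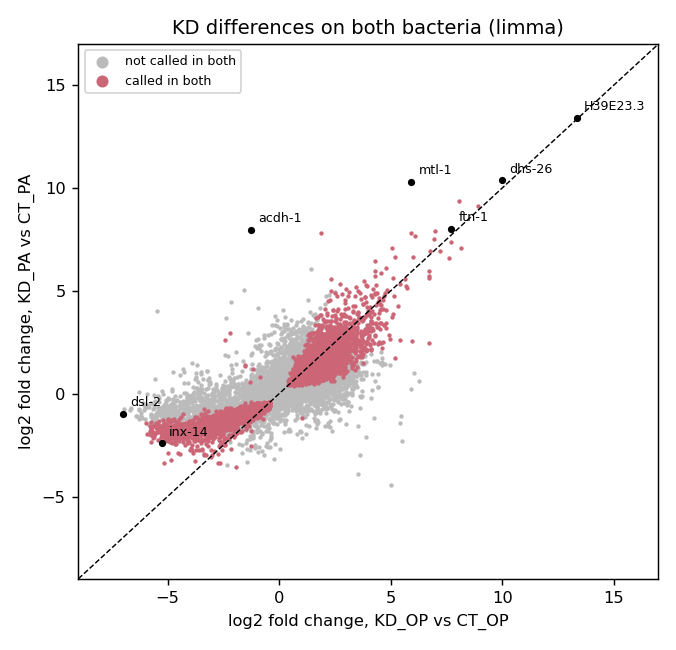
Log2 fold change of each of the 15488 genes in KD_OP against CT_OP (horizontal) and in KD_PA against CT_PA (vertical), with genes called in both comparisons coloured and the line of equal change dashed. inx-14 lies at -5.26 and -2.40 and H39E23.3 near the line at the top, where it had no reads in either CT group.

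The response of vector-treated worms to PA14 was read from CT_PA against CT_OP. Genes of the infection response were higher in CT_PA as groups. The 15 p38-linked effectors had a median log2 fold change of 1.57 and the 11 ZIP-2-linked genes one of 2.34, with camera adjusted p = 1.72e-07 and 1.45e-06, and adjusted p = 0.877 for both with an estimated correlation. Over all genes tested none of their members passed; adjusted over the list alone, 10 p38-linked genes rose and 1 fell, and 6 ZIP-2-linked genes rose. T24B8.5 was at 1.64 ± 0.29 (SE), C32H11.4 at 2.91 ± 0.63, zip-2 at 1.14 ± 0.26 and irg-3 at 3.48 ± 0.78, each with both CT_PA libraries above both CT_OP libraries. The only gene that passed over all genes was mtl-2, a metallothionein of the intestine, with 70.5 and 121 normalised reads in CT_OP and 1.13 and 0 in CT_PA, lower by a ratio of reads of 181 (exact 95% counting interval 32.1 to 7200; limma adjusted p = 0.014). It was not called without CT_OP 1, CT_OP 2, KD_OP 1, KD_OP 2 or CT_PA 2, with log2 fold changes from -6.54 to -5.45 over single libraries left out.

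Several other groups moved in the set test with PA14 in vector worms. Saposin-like proteins (median 0.53; 0.35 with 4 near-zero genes at the floor of 3 reads), intestinal genes (0.41) and glutathione S-transferases (0.21) were higher, with adjusted p = 0.00269, 0.00323 and 0.0466. Zygotic embryonic genes (-0.89), epidermal antimicrobial peptides (-0.75; -0.67 with 1 gene at the floor), cuticle collagens (-0.39; -0.30 with 17 genes at the floor), moulting genes (-0.23) and muscle genes (-0.19) were lower, with adjusted p = 2.26e-05, 0.00849, 0.00269, 0.0113 and 0.0466. With an estimated correlation the adjusted p was 0.877 for these lists and 0.986 for muscle. Each of these calls was lost when some single library was left out, and the CT_PA libraries differed. CT_PA 1 gave most of the change in saposin-like proteins (0.76 against 0.09 in CT_PA 2), glutathione S-transferases (0.45 against 0.02) and embryonic genes (-1.26 against -0.50), which were not called without it (adjusted p = 0.421, 0.646 and 0.421). Moulting genes were not called without CT_PA 1 either (adjusted p = 0.315), although their median was then larger, at -0.44. CT_PA 2 gave most of it in epidermal antimicrobial peptides (-1.59 against 0.02 in CT_PA 1), collagens (-0.70 against 0.03) and muscle genes (-0.45 against 0.11). Without CT_PA 2 these 3 lists (adjusted p = 0.795, 0.687 and 0.823, muscle with a reversed median of 0.11) and the intestine (0.0507, its median still 0.41) were not called. Other calls were lost with medians of similar or larger size. Without CT_OP 2 these were collagens (-0.31, adjusted p = 0.229), moulting genes (-0.34, 0.27), glutathione S-transferases (0.26, 0.131) and muscle (-0.27, 0.131). For muscle the same held without CT_OP 1 (-0.14, 0.081), KD_PA 1 (-0.19, 0.0536) or KD_PA 2 (-0.19, 0.0549). The 63 lysosomal genes had a median of 0.16 and a mean of -0.02 (adjusted p = 0.142; 6 rose and 2 fell when adjusted over the list alone), the Notch list -0.03 (adjusted p = 0.496; 0.01 when scaled to muscle and neuron genes) and the germline list -0.05 (adjusted p = 0.436). inx-14 differed by 0.16 ± 0.19 (adjusted p = 0.901).

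Single genes with large differences in CT_PA did not pass over all genes. The fatty-acid genes acdh-1 and acs-2 were at -10.20 ± 1.74 and -6.48 ± 0.88, the P450 gene cyp-35A3 at -3.14 ± 0.45, clec-10 at -3.25 ± 0.46, asp-13 at -2.30 ± 0.38 and noah-1, a gene of the apical matrix, at -1.29 ± 0.26. The small heat-shock gene hsp-17 was at 2.29 ± 0.31, gst-5 at 1.52 ± 0.23 and the lysozyme lys-1 at 1.47 ± 0.38. The lipase gene lipl-3 was lower by a ratio of reads of 79.6 (exact 95% counting interval 13.9 to 3180). The count of 1 gene by limma stood beside 1921 genes at an unadjusted p under 0.05, 0 genes by edgeR on the recovered reads, 444 by DESeq2 (311 higher, 133 lower) and 38 (30 higher, 8 lower) by limma without KD_OP 2 and KD_PA 1, whose spread enters the common estimate. In simulated data with the spread of all 8 libraries, limma recovered 22.1%, 78.8% and 98.5% of genes changed by 1, 2 and 3 in CT_PA (log2).

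The difference of inx-14 RNAi worms on PA14 from those on OP50 was read from KD_PA against KD_OP. Germline transcripts were higher in KD_PA. Of the 48 germline genes 47 rose, with a median log2 fold change of 2.49, 26 of 29 oocyte genes rose with a median of 2.79, and all 31 cell cycle genes rose with a median of 2.72. cpg-3 rose by 3.24 ± 0.18 (SE), pos-1 by 3.06 ± 0.17, cpb-3 by 2.85 ± 0.16, daz-1 by 2.77 ± 0.17, mcm-5 by 2.95 ± 0.17, cdk-1 by 2.94 ± 0.17 and inx-14 itself by 3.03 ± 0.19. Since inx-14 differed between these groups, a response to PA14 cannot be told apart here from a difference in the RNAi. Of 30 Notch genes 16 rose (median 1.05; 0.95 with its near-zero gene at the floor), including sygl-1 (2.75 ± 0.18) and lst-1 (2.06 ± 0.16). The camera test gave adjusted p = 2.01e-24, 1.61e-17, 7.02e-23 and 0.00033 for these lists, and adjusted p = 0.267 for each with an estimated correlation. Without KD_OP 2 and KD_PA 1 the germline and Notch medians were 2.30 and 1.01.

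The p38-linked and lysosomal lists showed no rise with PA14 in the RNAi worms in the fit of all 8 libraries. No p38-linked effector passed the test (median -0.29, camera adjusted p = 0.015, and adjusted p = 0.572 with an estimated correlation), with C17H12.6 at -1.48 ± 0.88 and dod-22 at -1.12 ± 0.62. With single libraries left out these ranged from -2.54 (without KD_OP 2) to -0.43 (without KD_OP 1) for C17H12.6 and from -1.89 (without KD_PA 2) to -0.35 (without KD_PA 1) for dod-22. In the lysosomal list only cup-5 rose, by 0.94 ± 0.17 (median -0.28, adjusted p = 4.68e-06, and adjusted p = 0.267 with an estimated correlation). Muscle and neuron genes had medians of -0.28 and -0.43 (adjusted p = 2.14e-05 and 9.41e-07, and adjusted p = 0.572 and 0.267 with an estimated correlation). Scaled to muscle and neuron genes, the p38-linked (0.03) and lysosomal (0.04) medians changed sign. The muscle median (0.04) was near 0 by the construction of that scaling. Without KD_OP 2 and KD_PA 1 the p38-linked median was 0.74, with 2 rises (adjusted p = 0.49), and dod-22 was at 0.01. The p38-linked call was also lost without KD_OP 2 (median 0.24, adjusted p = 0.231), without KD_PA 1 (0.31, adjusted p = 0.58) and under quantile normalization (adjusted p = 0.324). The ZIP-2-linked list had a median of 0.14 with 0 genes called (adjusted p = 0.269), 1.31 with 2 rises without KD_OP 2 and KD_PA 1 (adjusted p = 0.491) and -0.99 without KD_PA 2 (adjusted p = 0.00298). Of the C-type lectins 5 rose and 0 fell (median -0.28, 0.05 when scaled to muscle and neuron genes, adjusted p = 1.83e-05, and adjusted p = 0.267 with an estimated correlation). With KD_OP 2 and KD_PA 1 left out, medians were -0.18 for lysosomal, -0.64 for muscle, -0.54 for neuron and -0.09 for C-type lectin genes.

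Among the largest rises in KD_PA over KD_OP were dsl-2 (4.44 ± 1.00), Y106G6D.2 (4.25 ± 0.77) and timm-17B.2 (3.96 ± 0.35), a gene for mitochondrial protein import. rgs-8.2, R11.4 and bath-31 had no reads in KD_OP and were at least 8.86-fold, 7.63-fold and 6.13-fold higher. F48E3.6, F14D2.11, dot-1.5 and C46E10.8 were higher by ratios of reads of 58.1 (exact 95% counting interval 10 to 2330), 29.5 (7.82 to 250), 47.1 (8.05 to 1900) and 26.7 (8.82 to 132). T04A11.2 (-3.81 ± 0.72), K01C8.2 (-2.28 ± 0.68), C03F11.2 (-1.86 ± 0.59), F14D7.12 (-1.61 ± 0.50), cyp-35A3 (-1.44 ± 0.45), C17C3.15 (-1.40 ± 0.42), the galactosidase bgal-2 (-1.15 ± 0.34) and lact-4 (-1.14 ± 0.33) fell, and Y106G6A.4 and F17E9.3 were lower by ratios of 7.99 (2.43 to 41.4) and 9.99 (2.43 to 88.1). Of these falls only that of T04A11.2 was called whichever library was left out. Calls were lost on 8 of 8 omissions for C03F11.2 and F14D7.12, 7 for cyp-35A3 (-2.12 to -0.75) and Y106G6A.4, 5 for bgal-2 and lact-4, 4 for K01C8.2 and C17C3.15 and 3 for F17E9.3. Among the rises, dsl-2 was not called without KD_PA 1 (3.92), nor rgs-8.2 without KD_OP 1, KD_OP 2 or KD_PA 1.

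By limma 3803 genes passed, 3770 higher and 33 lower (99.1% higher), and 3650 (3310 higher, 340 lower) without KD_OP 2 and KD_PA 1. Quantile normalization gave 60.5% higher and a median of all genes of -0.20 in place of 0.13 (-0.06 in edgeR and 0.43 when scaled to muscle and neuron genes). Of the genes called here, 0 were also called in the same direction in CT_PA against CT_OP, where limma called 1, and across genes the PA14 differences of the vector and RNAi worms correlated with Pearson r = -0.112. That correlation was 0.173 without KD_OP 2 and KD_PA 1, and ranged from -0.301 (without KD_PA 2) to 0.078 (without KD_PA 1).

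Whether the RNAi difference depended on the bacteria could not be told apart here from the smaller fall of inx-14 in KD_PA. What was tested was the interaction, the difference in KD_PA minus that in KD_OP. It was positive for inx-14 (2.86 ± 0.28, SE; adjusted p = 0.000447) and for germline genes, of which 47 of 48 passed (median 2.60; cpb-3 2.87 ± 0.23), and for 27 of 29 oocyte genes (median 2.77; pos-1 3.04 ± 0.24). Of 30 Notch genes 17 passed, all positive (median 1.15; sygl-1 2.60 ± 0.26, lst-1 2.1 ± 0.22). It was negative for 3 of 15 p38-linked genes, 5 when adjusted over the list alone (median -1.76; T24B8.5 -1.93 ± 0.41, C32H11.4 -3.37 ± 0.89, C17H12.8 -1.76 ± 0.52). In the ZIP-2-linked list 1 of 11 passed, 0 when adjusted over the list alone (median -1.84; irg-3 -3.59 ± 1.11). The camera test gave adjusted p = 1.27e-21, 1.8e-15, 0.000553, 6.07e-06 and 0.000553 for these 5 lists, and adjusted p = 0.301, 0.301, 0.301, 0.301 and 0.343 with an estimated correlation. Of the named p38-linked and ZIP-2-linked genes, T24B8.5 lost its call without CT_OP 2 (-1.83). C32H11.4 lost it without CT_OP 1, CT_OP 2, KD_OP 2, CT_PA 1 or KD_PA 1 (range -4.27 to -2.47), and C17H12.8 (-2.28 to -1.24) and irg-3 (-4.84 to -2.34) without any of these or CT_PA 2. Without KD_OP 2 and KD_PA 1 the p38-linked median was -0.81 and the ZIP-2-linked -1.22, with 1 gene passing in each, and the germline median was 2.40.

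The largest positive interactions were those of the acyl-CoA dehydrogenase genes acdh-2 (9.51 ± 2.61) and acdh-1 (9.23 ± 2.46) and of zip-8 (6.35 ± 1.55), all with uneven KD libraries. tbx-8, a T-box factor gene of the embryo, and R11.4 had no reads in KD_OP and fitted interactions of 6.29 ± 1.07 and 6.20 ± 0.79, which are no bounds. mtl-2 was at 5.94 ± 0.68. The largest negative ones were Y53G8AM.5 (-5.45 ± 1.15), cld-9 (-4.33 ± 1.08), F15B9.6 (-4.28 ± 1.09), clec-27 (-4.19 ± 1.04) and W01C9.1 (-3.79 ± 1.13). With single libraries left out, calls were lost on 6 of 8 omissions for acdh-2 (6.8 to 12.23) and W01C9.1 (-4.81 to -2.77), 5 for clec-27, 4 for acdh-1 (6.19 to 12.27), zip-8 and F15B9.6 and 3 for cld-9. In all 3463 genes passed, 3160 positive and 303 negative (91.3% positive), and 2953 (2742 and 211) without KD_OP 2 and KD_PA 1. The positive share was 74.7% in edgeR and 66.1% under quantile normalization, with medians of all genes of -0.03 and -0.12 in place of 0.27 (0.54 when scaled to muscle and neuron genes), and the count was 1843 without CT_OP 1 and 2082 without CT_OP 2.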

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

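The tests that weigh explanations in this part were chosen only after the result was seen, while the interaction test was planned. The results given first were picked out because the difference between inx-14 RNAi and vector libraries itself differed between OP50 and PA14 by the interaction test in limma. This held for 3463 genes. Since inx-14 was itself among them, a dependence on the bacteria cannot be told apart from a difference in the RNAi. Values are log2, the difference on PA14 minus that on OP50, and fitted values of genes with 0 to 3 reads in a group depend on the pseudocount.

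Among the named genes, those of the germline, oocyte, cell cycle, innexin and Notch lists were positive: inx-14 2.86, inx-22 2.97, inx-21 3.16, inx-3 3.04, cpb-3 2.87, daz-1 2.71, pos-1 3.04, puf-5 2.94, cpg-3 3.08, lin-41 2.57, mcm-5 3.03, cdk-1 3.0, lst-1 2.1, sygl-1 2.60, apx-1 1.92 and lag-1 0.98. Genes with the largest falls on OP50 were positive as well: dsl-2 6.03, R11.4 6.20, Y106G6D.2 5.89, F48E3.6 5.95, skr-10 5.34, T25E12.6 5.26, btb-11 5.53, zip-8 6.35, skr-9 5.07 and clec-266 5.49. They were chosen by that fall, which enters the interaction with a minus sign. Their positive values were thus favoured by the choice and are no separate finding. Further positive genes were vha-18 2.76, tdc-1 2.37, rpl-11.1 3.0, sepa-1 4.48, mtl-2 5.94, acdh-1 9.23, acdh-2 9.51, asp-13 1.99 and tbx-8 6.29. Negative were T24B8.5 -1.93, C17H12.8 -1.76, C32H11.4 -3.37, irg-3 -3.59, hex-1 -0.84, vha-6 -0.97, Y53G8AM.5 -5.45, cld-9 -4.33, F15B9.6 -4.28, clec-27 -4.19 and W01C9.1 -3.79.

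By list, the median interaction was 2.60 for germline, 2.77 for oocyte, 2.77 for cell cycle, 1.15 for Notch and 0.63 for ribosomal genes. It was -1.76 for p38-linked, -1.84 for ZIP-2-linked, -0.39 for lysosomal, -0.35 for vacuolar ATPase, -0.15 for muscle, -0.40 for neuron and -0.67 for intestinal genes. Scaled to muscle and neuron genes these 7 were -1.48, -2.08, -0.11, -0.07, 0.13, -0.12 and -0.38, and called lysosomal genes turned from 2 positive and 5 negative to 4 positive and 1 negative. The muscle and neuron values are held near 0 by the construction of that scaling, so a muscle call lost there carries no weight. None of these lists was called with an estimated correlation, and several calls depended on single libraries or scaling. The ribosomal list lost its call without KD_OP 1 (adjusted p = 0.139) or KD_PA 2 (0.067). The muscle list lost it without KD_OP 1 (median 0.08, adjusted p = 0.442), CT_PA 1 (0.14, adjusted p = 0.427) or KD_PA 2 (-0.01, adjusted p = 0.147), under quantile normalization (adjusted p = 0.434) and with muscle and neuron scaling (adjusted p = 0.187). The vacuolar ATPase list lost it without CT_PA 1 (median -0.11, adjusted p = 0.0665) and under quantile normalization (adjusted p = 0.0656).

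The first pattern weighed was the place of KD_OP 2 and KD_PA 1 on the 263 genes that differed most between CT_PA and CT_OP. An exchange of the labels of KD_OP 2 and KD_PA 1 could not be told from other causes: KD_OP 2 lay 0.58 of the CT_PA minus CT_OP difference nearer to CT_PA than KD_PA 1, which restates the pattern and lies between 0 and the whole difference. Weak exposure of KD_PA 1 to PA14 as the whole cause, and a response of immune list genes alone, stayed open too. KD_OP 2 lay 0.45 above KD_OP 1 (0.43 outside those lists). Replicates differed by 0.01 in CT_OP and 0.24 in CT_PA (over 274 genes, not chosen for replicate agreement), and the larger value was taken as the spread. The gap was large against that of CT_OP, the control on the same bacteria. Each position rests on 1 library, with SE of 0.03 to 0.04 over genes. RNA of PA14-treated animals like those measured here, mixed into KD_OP 2, would raise its germline list. That list was lower in KD_OP 2 than in KD_OP 1 by a median of -0.58 (SE 0.04 over genes), where replicates of other groups differed by up to 0.23. This does not exclude mixing, because the level of KD_OP 2 without mixing is not known and each value rests on 1 library. If the labels were exchanged, the germline levels of -4.15 and -4.82 in KD_OP and -2.03 and -1.80 in KD_PA would differ within each bacterial condition rather than between them, which stays open, and no biological explanation beyond these was tested.

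The second pattern was the fall of inx-14 together with other germline transcripts. Among 77 germline and oocyte genes 1 fell as much as inx-14 in KD_OP and 0 did in KD_PA, inx-14 lying -0.65 and -0.54 from their medians. Some gene must fall most, so this rank does not exclude a loss of germline transcripts as the only cause. With single libraries left out, inx-14 ranged from -5.48 to -5.04 in KD_OP and cpg-3 from -5.04 to -4.98. In KD_PA inx-14 ranged from -2.57 to -2.23 and lin-41 from -2.14 to -1.86. Silencing of inx-14 with no effect on other transcripts was excluded by germline medians of -4.46 and -1.83. A combination of both could account for the values; reads from the RNAi clone itself were not tested.

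The third pattern was the higher level of immune and lysosomal lists in KD_OP than in CT_OP. A larger share of somatic RNA, as the germline shrinks, may account for the lysosomal list, whose median relative to muscle and neuron genes was 0.17 (lower quartile -1.05). For the p38-linked list the same explanation as the whole cause was made less likely, at 1.6 (lower quartile 1.18), with 6 of 15 genes called higher. It was not excluded, since the rule was set after the values were seen. The quartile is also taken over genes that vary together (estimated correlation 0.447). The library KD_OP 2 as the cause was made less likely but not excluded. From the deposited values the p38-linked list lay at 0.28 and -0.28 in the CT_OP libraries. Without KD_OP 2 its median relative to muscle and neuron genes was 1.25 (lower quartile 0.60), which rests on the single library KD_OP 1. In the infected worms the p38-linked median on that scale was -0.14, with 1 of 15 genes higher.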

How the results depend on the processing

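The tests with edgeR, DESeq2, muscle and neuron scaling and the omission of 2 libraries together were chosen only after the result was seen. Numbers of called genes for KD_OP against CT_OP and KD_PA against CT_PA stayed within 1.5 times of 11679 and 9450 throughout, from 10310 to 11754 and from 7464 to 9726 with single libraries left out. The log2 fold change of inx-14 then ranged from -5.48 to -5.04 and from -2.57 to -2.23. A library left alone in its group is assumed to vary like the others.

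For CT_PA against CT_OP, 1 gene was called, but 0 with log2(value + 0.1), quantile normalization, no variance trend or edgeR, 3 with scaling to muscle and neuron genes, 36 with only the 2 groups, 38 without KD_OP 2 and KD_PA 1, 180 with the replicate block, 444 with DESeq2, and from 0 to 38 with single libraries left out. Genes called the same way in both PA14 comparisons were 0, but 5 with DESeq2 (0 higher in both against 74.2 by chance, and 20 opposite), 9 with the replicate block (2 higher in both against 26.8 by chance, and 3 opposite), 29 without KD_OP 2 and KD_PA 1, and 0 to 2 with single libraries left out. KD_PA against KD_OP gave 2202 genes in edgeR without KD_PA 2 in place of 3803. The interaction gave 1843 to 3909 genes with single libraries left out in place of 3463. The cause was not tested.

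For the p38-linked list in KD_PA against CT_PA, camera gave adjusted p from 0.000246 to 0.141 with single libraries left out. Directions reversed with scaling to muscle and neuron genes for vit-5 in KD_OP (-0.07), vha-6 in KD_PA (-0.67) and the vacuolar ATPase list in KD_OP (median -1.12, adjusted p = 0.0971), by the construction of that scaling. They also reversed for dod-22 in KD_PA against KD_OP without KD_OP 2 and KD_PA 1 (0.01; from -1.89 with single libraries left out) and for muscle genes in CT_PA against CT_OP without CT_PA 2 (adjusted p = 0.823; 5.37e-05 without CT_PA 1). The p38-linked list reversed in KD_PA against KD_OP without KD_OP 2 and KD_PA 1 (median 0.74, adjusted p = 0.49), and in KD_PA its median (-0.14) and the lysosomal (-0.06) changed sign with muscle and neuron scaling. Of 171 results on named genes, 144 kept direction and call without KD_OP 2 and KD_PA 1 (22 weaker, 4 stronger, 1 reversed), 148 without KD_PA 1 and with DESeq2, and 149 with muscle and neuron scaling. Changes of 1 on the log2 scale were recovered in 11.8% of simulated genes for KD_OP against CT_OP. That simulation changed few genes (68 by 1, 66 by 2 and 66 by 3), whereas 11679 of 15488 passed in the measured comparison. Its adjusted threshold was therefore stricter, and the rate does not carry over to that comparison. A gene not called is still not shown to be unchanged.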

Other observations

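Tests of gene classes and chromosomes in this part were chosen only after the result was seen. Further groups of somatic genes were higher in KD_OP than in CT_OP. Of 129 C-type lectins 73 rose and 11 fell (median log2 fold change 1.75; 1.69 with near-zero genes at the floor), of 24 saposin-like proteins 14 rose (1.44; 1.29) and of 26 pals genes 16 rose (2.0; 1.6). Of 70 cytochrome P450s 39 rose and 5 fell (1.57; 1.53), of 62 UDP-glucuronosyltransferases 41 and 4 (1.46), of 40 glutathione S-transferases 27 and 3 (1.91), of 28 SKN-1 and DAF-16 stress targets 19 and 3 (1.81), of 40 fatty-acid genes 25 and 5 (1.19), of 23 metal-handling genes 19 and 2 (1.88) and of 125 collagens 55 and 15 (1.05; 1.00). These 10 lists were called by camera (adjusted p from 4.08e-06 for lectins to 0.00296 for collagens), but not with an estimated correlation (adjusted p = 0.197 and 0.602 for these 2), and the medians of P450s (-0.07), UDP-glucuronosyltransferases (-0.19), fatty-acid genes (-0.47) and collagens (-0.32) changed sign when scaled to muscle and neuron genes. On that scale the others fell to 0.17 for lectins (18 rose, 17 fell), 0.05 for saposin-like proteins (3 and 2), 0.38 for glutathione S-transferases (4 and 9), 0.17 for stress targets (8 and 10), 0.23 for metal handling (5 and 5) and 0.57 for pals genes (5 and 2). Zygotic embryonic genes fell in 45 of 56 cases and rose in 7 (median -3.80, -3.09 with 19 near-zero genes at the floor; adjusted p = 0.000643, and adjusted p = 0.537 with an estimated correlation). Not called were somatic gonad and sheath (9 rose, 4 fell, median 0.55), heat-shock proteins (7 and 4, 1.22), vitellogenins (2 and 0, 0.73, but -0.01 under quantile normalization; 0 when adjusted over the list alone), epidermal antimicrobial peptides (1 and 0, 0.45), sperm genes (4 and 7, 0.23 with a mean of -0.40), moulting genes (9 and 10, 0.17 with a mean of -0.33), histones (9 and 13, -0.13; 0.05 at the floor) and unfolded-protein responses (4 and 13, -0.64). When scaled to muscle and neuron genes the medians of the first 6 of these were negative. On that scale the unfolded-protein list was called, with 22 of 23 genes lower (median -2.29, camera adjusted p = 0.00419). Under quantile normalization the somatic gonad list was called (median 1.22, camera adjusted p = 0.0376). Leaving out KD_OP 2 and KD_PA 1, the somatic gonad list (median 0.80, adjusted p = 0.0289) and heat-shock proteins (11 rose, 4 fell, median 2.1, adjusted p = 0.0286) were called and the histone median was -1.41, with heat-shock levels of 2.1 in KD_OP 1 and 0.17 in KD_OP 2. Leaving out KD_OP 2 alone called the same 2 lists (adjusted p = 0.031 and 0.0413), which with an estimated correlation over all libraries had adjusted p = 0.602 and 0.702, and without KD_OP 1 the histone median was 0.04.

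Classes outside the fixed lists were also compared, 84 by name. In KD_OP all 25 nucleoporin genes (npp, median -3.1) and all 42 mitochondrial ribosomal mrpl genes (-1.96) fell, as did 96 of 102 fbxb F-box genes (-4.19), while 29 of 30 flp neuropeptide genes rose (1.74, 0.10 when scaled to muscle and neuron genes). In CT_PA against CT_OP the fbxb genes had a median of -1.56 (camera adjusted p = 1.55e-21, and adjusted p = 0.993 with an estimated correlation), with none called. Of the genes on chromosome X 52.8% rose and 17.3% fell in KD_OP (median 1.11, but -0.48 when scaled to muscle and neuron genes), against 24.9% and 55.6% on chromosome I (-1.21). These were the extremes, and the autosome V had a median near that of X, with 42.2% and 28.7% (0.91, but -0.62 when so scaled).

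Low acdh-1 and hphd-1 in CT_PA, at -10.20 and -3.95 against CT_OP, raised the question whether the whole propionate shunt was lowered on PA14, a pathway that is turned down where vitamin B12 is supplied. This test was planned before its 3 genes were looked at, and the shunt genes lie outside the naming rule. ech-6, hach-1 and alh-8 had a median of -1.11 (-1.70, -1.11 and -0.70), which may point to the whole shunt in vector worms, although none of the 5 genes was called. In KD_PA against KD_OP the differences were smaller and none was called, with uneven KD libraries. There acdh-1 was at -0.97, ech-6 at -0.32, hach-1 at -0.11, hphd-1 at -0.30 and alh-8 at -0.29.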
